A study of Mus musculus with 4 samples.

How the data were processed

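Per the labels, total RNA from the hearts of 4 mice was measured on 4 Affymetrix Mouse Genome 430 2.0 arrays, although the arrays labelled NTg 1 and Tg-Sirt1 1 were near-identical. Per the labels, 2 mice were wild type, called NTg 1 and NTg 2, and 2 carried a Sirt1 transgene, called Tg-Sirt1 1 and Tg-Sirt1 2. Per the labels' protocols, mice were killed with pentobarbital at 120 mg/kg and the hearts were removed and snap frozen. Age, sex, transgene promoter and line are not given in the sources used here.

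The deposited values were on the log2 scale with 2 decimals, 1 value per probe set and array. The submitters' processing notes name RMA and Affymetrix Expression Console, without versions. RMA corrects the background, quantile normalizes the arrays and summarises the probes of each probe set, so that a change in total RNA content is removed and differences of dim probe sets are damped. Scanner files were not used here, so detection calls, scan dates and the signal over background of each probe set are not given. The number of arrays limits the precision.

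Of 45101 probe sets, 64 control probe sets were left out of the tests, which left 45037. Probe sets were named from the platform annotation, in which 34945 of the tested probe sets had 1 gene symbol, 932 had several and 9160 had none here. The Entrez identifiers of 34741 probe sets matched the RefSeq gene table of the mouse assembly GRCm38.p6, and 0 symbols changed through this match. No coordinates were used. For each of 18193 genes, the probe set with 1 symbol and the highest mean over the 4 arrays represented the gene.

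The Tg-Sirt1 arrays were compared with the NTg arrays in limma 3.58.1 under R 4.3.3, with lmFit and eBayes without trend or robust prior, on the deposited log2 values. P-values were two-sided and adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The residual degrees of freedom were 2 and the prior added 3.10 over probe sets. A fold change is the mean of the Tg-Sirt1 arrays minus the mean of the NTg arrays in log2 units, and SD values are over the 2 arrays of a label. An exact two-sided permutation test of 2 against 2 arrays cannot give a p below 0.333. The 44 lists, 28 of gene groups and 16 of cell type markers, held 1015 distinct symbols, some of them on several lists, and 913 distinct genes were measured. They were tested with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation and with fry, each adjusted over the 44 lists.

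Tests, lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule named Sirt1, the 12 largest rises and the 12 largest falls past the threshold with both Tg-Sirt1 arrays beyond both NTg arrays, up to 4 members per list by smallest p, and Nppa, Nppb, Myh6, Myh7, Ppargc1a, Cat and Sod2. Open places went to the genes of smallest unadjusted p with the same separation and an absolute log2 fold change of at least 0.5. Symbols that are only clone names were passed over. The 31 named genes, Sirt1 included, had 45 other probe sets, of which 12 differed in sign from the representative and 0 did so at an unadjusted p under 0.05. The 12 include a Syn2 probe set with a log2 fold change of 0.

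All pairs of arrays were compared over the 45037 probe sets and over 18 spike-in control probe sets. Differences between 2 single arrays were described without a test. For lists, the median of such a difference was ranked among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins, as a description of those arrays. The differences between single arrays, the rule that took the 12 largest of them per direction, and the fits that counted the near-identical arrays once were chosen after seeing the data.

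The fit was tested on simulated data for 18193 genes, with 100 genes changed by 1 log2 unit and 100 by 2 log2 units. With 4 separate arrays, 11% of the smaller and 92% of the larger changes were recovered and 2 unchanged genes were called. When the simulated Tg-Sirt1 1 array was a copy of NTg 1, 0% of either size was recovered, 0 unchanged genes were called, and the median estimate of a change of 2 log2 units was 0.99. Alternatives covered the replicate number as a block, each array left out, a filter on dim probe sets, a second quantile normalization, centring on medians, an offset of 16 on the linear scale, an intensity trend with a robust prior, an unmoderated test, other thresholds, other ways to choose the probe set of a gene and other list tests.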

Results

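The series asked how a Sirt1 transgene alters gene expression in the mouse heart. Sirt1 is an NAD-dependent protein deacetylase. The data were 4 arrays of heart RNA, 2 labelled NTg from wild type mice and 2 labelled Tg-Sirt1 from transgenic mice. The median log2 value was 6.23 on NTg 1, 6.30 on NTg 2, 6.24 on the array labelled Tg-Sirt1 1 and 6.22 on Tg-Sirt1 2. Because the arrays NTg 1 and Tg-Sirt1 1 were near-identical, samples are called by the names of their arrays throughout, and no array was moved to another group.

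Sirt1 itself was not higher on both arrays labelled Tg-Sirt1. Its only annotated probe set read 7.93 on Tg-Sirt1 2, but 7.16 on the array labelled Tg-Sirt1 1, against 7.30 on NTg 1 and 7.17 on NTg 2. The mean was 7.55 ± 0.54 (SD, n = 2) in Tg-Sirt1 and 7.24 ± 0.09 (SD, n = 2) in NTg. The log2 fold change was 0.31 with a standard error of 0.27 and a 95% confidence interval from -0.39 to 1.01, and its adjusted p in limma was 0.996. Without Tg-Sirt1 2 the log2 fold change was -0.08, and without the array labelled Tg-Sirt1 1 it was 0.70. With the near-identical pair averaged and counted once, it was 0.73 with the pair as NTg (limma adjusted p = 0.769) and 0.41 with the pair as Tg-Sirt1 (0.692). The part of the transcript that this probe set covers was not determined here, and a transgene made from a cDNA can lack the untranslated part, so the probe set need not check the labels. Of the other sirtuins, the mitochondrial Sirt3 read 10.12 on NTg 1, 9.82 on NTg 2, 10.09 on the array labelled Tg-Sirt1 1 and 10.08 on Tg-Sirt1 2. The mitochondrial Sirt5 had a log2 fold change of 0.19 and the nuclear Sirt6 one of -0.17 (0.02 and -0.08 without NTg 2), and 5 of the 7 sirtuins measured had a higher Tg-Sirt1 mean (median 0.09, camera adjusted p = 0.746).

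The arrays labelled NTg 1 and Tg-Sirt1 1 gave almost the same value for nearly every transcript, whereas the other 5 pairs differed widely. Myosin heavy chain Myh7, the slow isoform that is high in the fetal mouse ventricle, read 11.65 and 11.64 on this pair, against 13.27 on NTg 2 and 10.89 on Tg-Sirt1 2. Skeletal alpha-actin, Acta1, read 7.37 on NTg 1 and 7.23 on the array labelled Tg-Sirt1 1, against 12.17 on NTg 2 and 6.46 on Tg-Sirt1 2. Over 45037 probe sets the SD of the differences within this pair was 0.0759 log2 units and the largest difference was 0.48, so that 0 probe sets lay over 2-fold apart. In the other 5 pairs the SD ran from 0.342 to 0.405 and 551 to 1101 probe sets lay over 2-fold apart. The correlation across probe sets, which are not independent replicates, was r = 0.9993 in this pair and 0.9792 to 0.9862 in the others. The 2 arrays of a label differed at 574 probe sets by over 2-fold in NTg and at 911 in Tg-Sirt1.

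**Figure D1:**
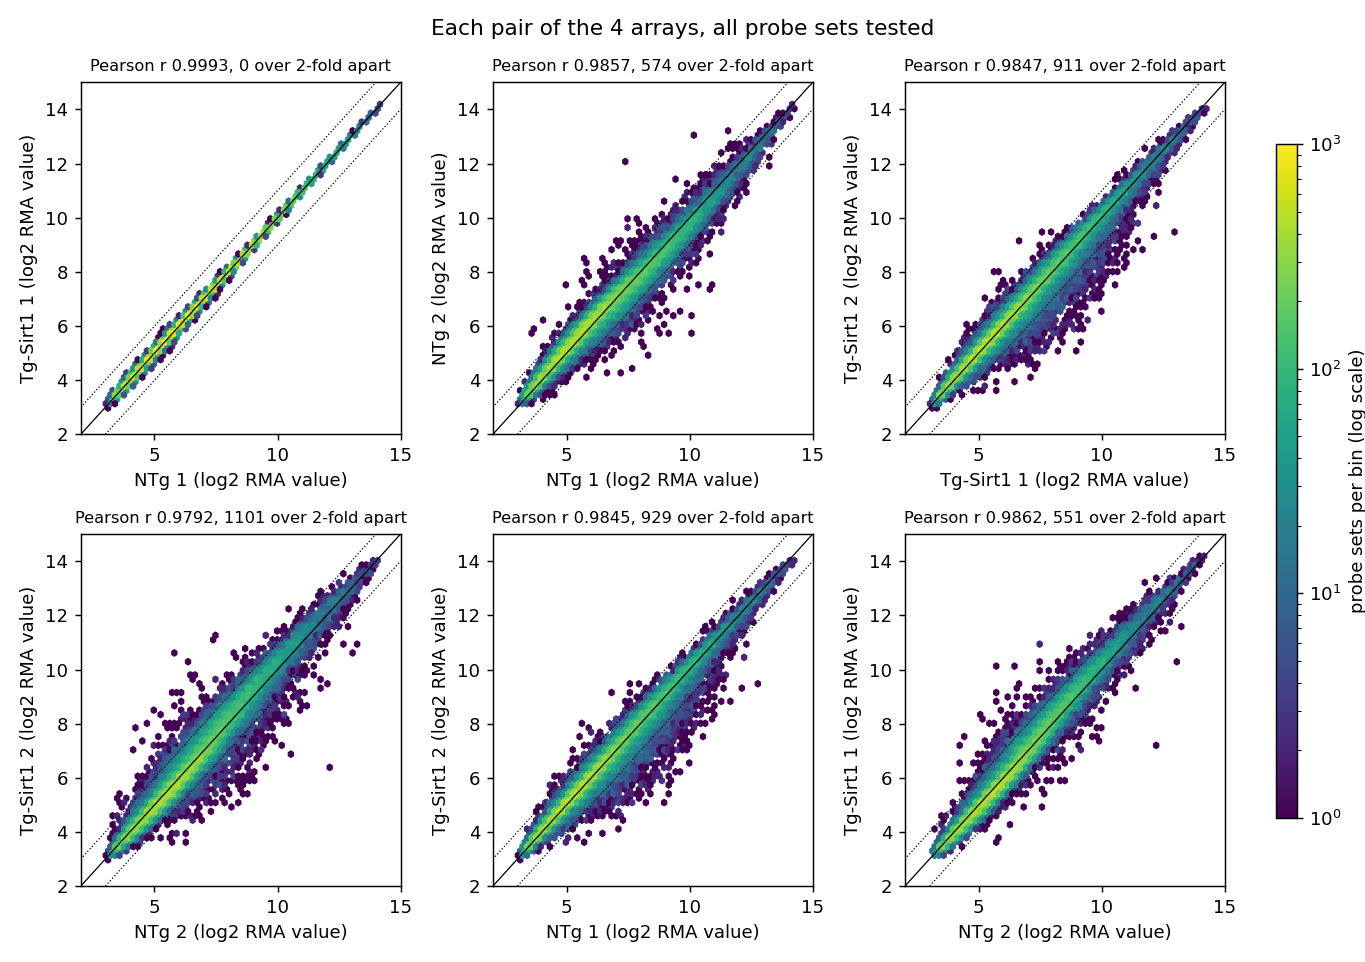
Log2 RMA values of each pair of the 4 arrays over all tested probe sets, with the colour giving the number of probe sets per bin on a log scale, a solid line at equality and dotted lines at a 2-fold difference. NTg 1 and Tg-Sirt1 1 have 0 probe sets beyond the dotted lines, and the other pairs have 551 to 1101.

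Between the labels, no gene passed the test. The genes with the lowest p on the higher side included Rasl2-9, a Ran-like small GTPase (log2 fold change 0.82), the histone gene H3c11 (1.27) and Acsl4, a long-chain acyl-CoA synthetase (1.05). On the lower side were Zbtb16, a zinc finger transcription factor (-0.97), Myh7 (-1.20), Acta1 (-2.93) and Cdkn1a, the cell cycle inhibitor p21 (-0.84). In limma, 0 of 45037 probe sets passed an adjusted p of 0.05 (lowest 0.996), and 28 had an unadjusted p under 0.05, where 2252 are expected by chance. At the level of genes 0 of 18193 passed (lowest 0.994), and 10 had an unadjusted p under 0.05, where 910 are expected by chance. The Tg-Sirt1 values lay wholly above or below the NTg values at 20.7% of genes, against 33.3% by chance. When 1 array equals an array of the other label, the ordinary t of 2 against 2 cannot exceed 1.41 in size, so this test had next to no power, and an absence of calls does not show that the hearts were alike. With the pair averaged and counted once under either label, the other label is left with 1 array, whose spread is taken from the first. Such fits add no evidence that the hearts were alike.

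The places for named genes were therefore filled by genes that did not pass, 12 from 102 with a higher and 12 from 18 with a lower Tg-Sirt1 mean. Rasl2-9 had the smallest p. It read 6.78 on NTg 1, 6.25 on NTg 2, 7.21 on the array labelled Tg-Sirt1 1 and 7.46 on Tg-Sirt1 2, with a standard error of 0.22, an unadjusted limma p of 0.00951 and an adjusted p of 0.994. Its difference of 0.43 between the array labelled Tg-Sirt1 1 and NTg 1 compares with a largest difference of 0.48 among all probe sets of that pair. The RNA-binding protein gene Mex3b had a log2 fold change of 0.56, the small GTPase gene Rab17 0.55, Particl 0.51 and Shisa2 0.57. H3c11 read 6.71 and 5.55 on NTg 1 and NTg 2 and 6.86 and 7.93 on the Tg-Sirt1 arrays. Acsl4 read 7.27 and 6.13 on the NTg arrays and 7.39 and 8.10 on the Tg-Sirt1 arrays. The guidance factor gene Sema3a (0.79), the lymphatic growth factor gene Vegfc (0.63), the complement regulator gene Cd55 (0.77), Phldb2 (0.61) and the folate enzyme gene Aldh1l1 (0.61) completed the higher side. These 5 values rested largely on NTg 2: without it they were 0.32, 0.32, 0.30, 0.28 and 0.24, and without NTg 1 they were 0.93 to 1.27. For the 12 genes on this side, unadjusted p ran from 0.00951 to 0.0582.

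On the lower side unadjusted p ran from 0.0589 to 0.0967. Zbtb16 read 10.08 and 10.89 on NTg 1 and NTg 2, and 10.06 and 8.98 on the arrays labelled Tg-Sirt1 1 and 2. Cdkn1a read 8.64 and 9.97 on the NTg arrays and 8.52 and 8.41 on the Tg-Sirt1 arrays. Without NTg 2 the log2 fold changes of Acta1, Myh7 and Cdkn1a were -0.53, -0.39 and -0.18, and without NTg 1 they were -5.33, -2.01 and -1.51. The representative probe sets of several of these genes were low on Tg-Sirt1 2 alone. Gdap10 read 5.96 there, against 7.95 to 8.59 on the other arrays. The ribosomal protein gene Rpl27a read 6.54 (against 7.66 to 8.20) and Zfp207 7.89 (against 9.08 to 9.36). The glutathione cycle enzyme gene Oplah read 7.08 (against 8.24 to 8.48) and the splicing cofactor gene Son 10.10 (against 10.82 to 11.09). Dimmer probe sets did not all share this. Some of Son were highest on Tg-Sirt1 2, such as 9.13 against 8.69 to 8.88. Others of Son were lowest there, such as 7.14 against 7.32 on NTg 2. A Zfp207 probe set read 8.75 there, between 8.40 on NTg 2 and 9.09 on the array labelled Tg-Sirt1 1. Another of Rpl27a read 5.52 on both Tg-Sirt1 arrays. The synapsin gene Syn2 had a log2 fold change of -0.54, the focal adhesion gene Tes -0.57 and Lrrc4b -0.52. Tg-Sirt1 2 also had the largest 3' minus 5' control signal of the 4 arrays for Actb (1.92 log2 units) and Gapdh (1.34), where a larger value means less 5' signal relative to 3' signal.

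**Figure D2:**
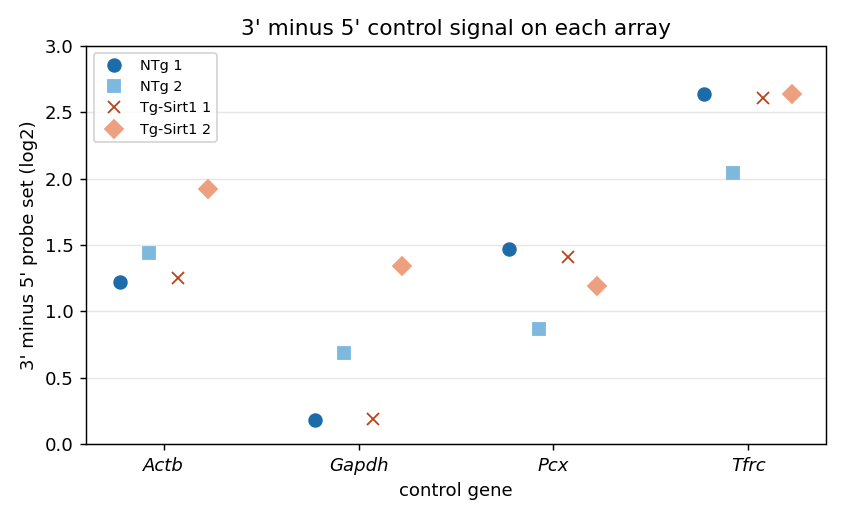
Difference in log2 units between the 3' and the 5' control probe set of 4 control genes on each array, with NTg 1 as circles, NTg 2 as squares, Tg-Sirt1 1 as crosses and Tg-Sirt1 2 as diamonds. Tg-Sirt1 2 is highest for Actb (1.92) and Gapdh (1.34) but not for Pcx (1.19), and it equals NTg 1 for Tfrc (2.64).

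The markers of cardiac load and oxidative defence named in advance did not pass either. The natriuretic peptide genes had log2 fold changes of 0.04 ± 0.25 (SE) for Nppa and -0.46 ± 0.25 (SE) for Nppb. Myh6, the adult myosin heavy chain, read 13.86 to 13.93 on the 4 arrays (log2 fold change -0.03 ± 0.14, SE). A dimmer probe set of Myh6 read 7.60 on Tg-Sirt1 2, against 9.66 on NTg 2 and 10.49 on the array labelled Tg-Sirt1 1, and the mean over both probe sets gave a log2 fold change of -0.53. The mitochondrial coactivator gene Ppargc1a had -0.06 ± 0.21 (SE), the catalase gene Cat -0.32 ± 0.26 (SE) and the superoxide dismutase gene Sod2 0.03 ± 0.14 (SE). All of these had an adjusted limma p of 0.994. The sign was not the same in every setting for Nppa, Myh6, Ppargc1a, Cat and Sod2.

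**Figure D3:**
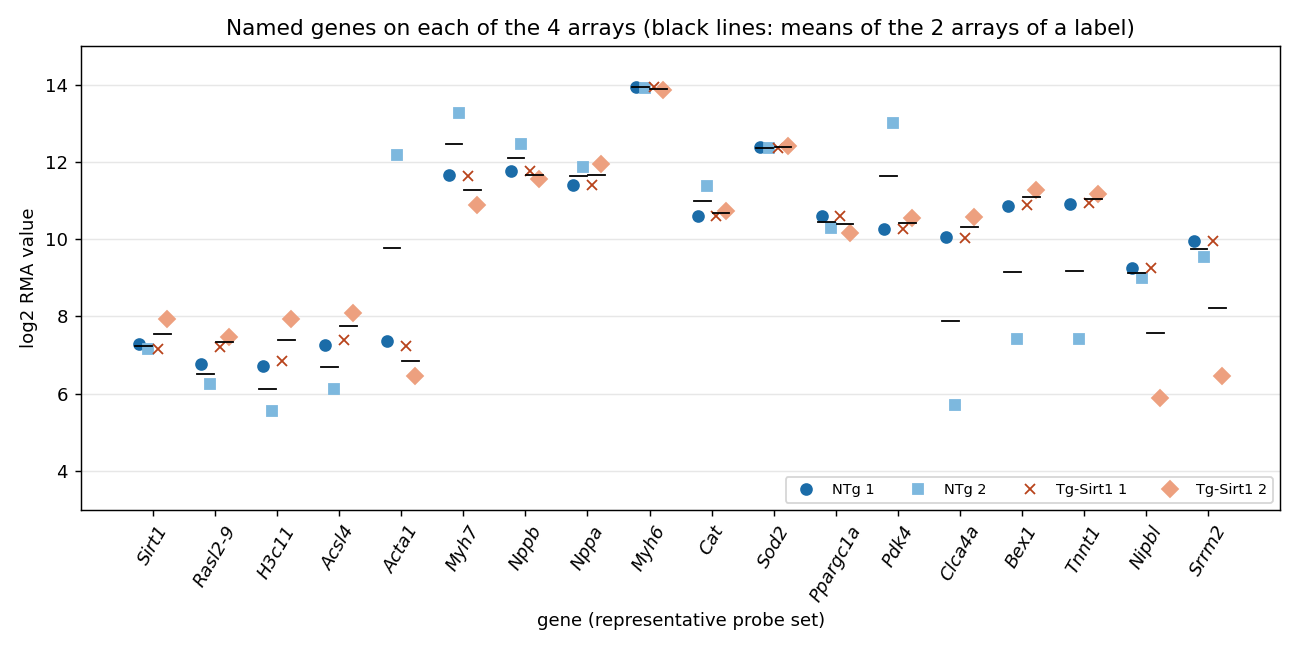
Log2 RMA values of 18 genes on the 4 arrays, with NTg 1 as circles, NTg 2 as squares, Tg-Sirt1 1 as crosses, Tg-Sirt1 2 as diamonds and black lines at the mean of the 2 arrays of a label. For Acta1, Pdk4, Clca4a, Bex1 and Tnnt1, NTg 2 stands apart from the other 3 arrays, and for Nipbl and Srrm2 Tg-Sirt1 2 does.

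Genes of fatty acid oxidation and PPAR targets were lower as a group in the Tg-Sirt1 arrays, with 31 of 39 measured members lower, a median log2 fold change of -0.13 and a camera adjusted p of 4.06e-05. With an estimated correlation the adjusted p was 0.991. Members included the lipase genes Lipe (log2 fold change -0.59) and Pnpla2 (-0.36), the lipoprotein receptor gene Vldlr (-0.38) and Mlycd, the malonyl-CoA decarboxylase gene (-0.30), which were -0.15, -0.17, -0.14 and -0.16 without Tg-Sirt1 2 and -0.42, -0.21, -0.24 and -0.17 without NTg 2. None of the 39 members passed, and neither did any member of another list, over all genes or adjusted over the list alone. Without NTg 2 the median of this group was -0.015. It was -0.19 without NTg 1, -0.19 without the array labelled Tg-Sirt1 1 and -0.085 without Tg-Sirt1 2. The last of these fits keeps only the near-identical partner of NTg 1 under the Tg-Sirt1 label. It is thus nearly a difference between the 2 NTg arrays.

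The other 3 lists past the threshold in camera were the cytosolic ribosomal proteins (31 of 36 members higher, median 0.11), the neutrophil markers (7 of 8 lower, median -0.15) and the Schwann cell and neuron markers (8 of 8 lower, median -0.18), each with an adjusted p of 0.04 and of 0.991 with an estimated correlation. Rpl14 (0.39), Rpl12 (0.44) and Rps9 (0.36) had the lowest p within the ribosomal list, and without NTg 2 they were 0.32, 0.22 and 0.00. The Rpl14 probe set was dim, at 5.26 to 5.90, below the median of each array. That of Rpl12 read 5.91 to 6.80, and that of Rps9 11.26 to 11.98. Only 36 of the 64 genes on the ribosomal list were measured. Rpl27a, a ribosomal protein gene that is not on it, had a lower p and went the other way (-0.86). The calprotectin genes S100a8 and S100a9 read 7.55 and 8.15 on NTg 2, against 5.64 to 6.10 and 6.39 to 6.77 on the other 3 arrays. The glial genes S100b (-0.26), Sox10 (-0.18) and Mbp (-0.18) had their highest value on NTg 2 as well. Without NTg 2 the medians of the 3 lists were -0.005, 0.065 and 0.035. They were 0.12, -0.18 and -0.16 without the array labelled Tg-Sirt1 1, and 0.26, -0.39 and -0.36 without NTg 1. Without Tg-Sirt1 2 they were 0.15, -0.185 and -0.16, but the only array then left under that label is near-identical to NTg 1. That fit is nearly a difference between the 2 NTg arrays. The fit without NTg 2 is nearly a difference between the 2 Tg-Sirt1 arrays. After a second quantile normalization the ribosomal list had a median of 0.06 with 24 members higher and 12 lower (adjusted p = 0.286), the neutrophil list a median of -0.14 (0.164) and the Schwann cell and neuron list one of -0.20 (0.0491). Without dim probe sets the ribosomal list had an adjusted p of 0.296, with the mean over all probe sets of a gene the Schwann cell and neuron list had 0.135, and without _x_at and _s_at probe sets the neutrophil list had 0.0646 and the Schwann cell and neuron list 0.0922. In fry, 0 of 44 lists passed (lowest unadjusted p 0.2), and 9 lists had an unadjusted camera p under 0.05. The near-identical pair limits the average of a list as it limits a single gene, so fry had little power. Its absence of calls does not show that the lists were alike.

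With NTg 1 and Tg-Sirt1 1 near-identical, a fold change nearly equals the sum of its values without NTg 2 and without Tg-Sirt1 2. At least 1 of these 2 values must then be smaller or of the other sign. The counts for single list members show only which array it was. Of the 171 genes that were among the 4 of smallest p on a list, 129 had a fold change over 1.5 times smaller or of the other sign without NTg 2, 24 of them of the other sign, and 85 did so without Tg-Sirt1 2, 14 of them of the other sign. Among metabolic lists that did not pass, cholesterol and lipid synthesis had a median of 0.17 with 19 of 28 members higher (camera adjusted p = 0.0664), among them the sterol regulator gene Srebf1 (0.47) and the desaturase gene Scd1 (0.50), which were 0.07 and 0.05 without NTg 2. Glucose uptake and glycolysis had a median of 0.11, with Pfkfb2 at 0.50 and the glucose transporter genes Slc2a1 at 0.35 and Slc2a4 at -0.28 (0.31, 0.18 and -0.27 without NTg 2, and 0.18, 0.18 and -0.03 without Tg-Sirt1 2). Nuclear-encoded oxidative phosphorylation genes had a median of 0.04 with 52 of 73 higher (a median of 0.005 with 39 of 73 higher after a second quantile normalization, and 60 higher after centring), citric acid cycle and pyruvate dehydrogenase genes 0.03, mitochondrial biogenesis and transcription genes 0.05, and NAD metabolism genes 0.06. Circadian clock and output genes had a median of 0.10, with the clock output gene Dbp at 0.70 and Per3 at 0.51, both 0.09 without NTg 2.

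Fetal and hypertrophy genes had a median of 0.03 but a mean of -0.13, with Acta1 and Myh7 far lower and 12 of 18 members higher, but 8 of 18 with a median of -0.02 after a second quantile normalization. The members of low p included the fetal troponin gene Tnni1 (0.45, and 0.20 without NTg 2). Adult contractile and calcium handling genes had a median of -0.02, with the titin-cap gene Tcap at -0.42 and the kinase gene Camk2d at 0.40 (-0.28 and 0.14 without NTg 2, -0.15 and 0.27 without Tg-Sirt1 2), and cardiac ion channels and conduction genes had -0.0025, with Kcnd2 at 0.46 and Abcc9 at 0.53 (0.23 and 0.08 without NTg 2). The extracellular matrix and fibrosis list had a median of 0.16 (28 of 41 higher, and 0.05 with 26 higher after a second quantile normalization), with Col8a1 at 0.60, which was 0.17 without NTg 2. Thbs4 on this list read 8.72 on NTg 2 and 10.76 to 10.81 on the other 3 arrays. Hypoxia and angiogenesis genes had 0.12, with Angpt1 at 0.90 and Hif1a at 0.42 (0.11 and 0.14 without NTg 2). Growth factor and PI3K-Akt-mTOR signalling genes had 0.03, and histone deacetylases and acetyltransferases 0.04.

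Stress and immune lists did not pass. Oxidative stress defence genes had a median of 0.06, with the superoxide dismutase gene Sod1 at 0.50 (0.28 without NTg 2) and the glutathione synthesis gene Gclm at -0.40 (-0.04 without Tg-Sirt1 2). Heat shock proteins had 0.12, with Hspb7 at -0.65 and the chaperone genes Hspe1 at 0.47 and Hspa1b at 0.56 (camera adjusted p = 0.229), which were -0.34, 0.23 and 0.31 without NTg 2. FoxO-regulated genes had 0.04, with Sesn3 at 0.64, Cdkn1a at -0.84 and Fbxo32 at 0.50 (0.23, -0.18 and 0.11 without NTg 2). The p53-regulated and apoptosis genes had 0.10, with Cdkn1a again the member of lowest p and lower, while Bcl2 read 7.26 on NTg 2 and 8.82 to 8.91 on the other 3 arrays. The medians were 0.03 for the unfolded protein and integrated stress response, 0.04 for autophagy and mitophagy, 0.13 for the proteasome, 0.06 for the cell cycle, -0.04 for NF-kB and inflammatory genes, 0.005 for immediate early genes and 0.06 for interferon-response genes.

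Cell type markers other than the 2 lists above did not pass. All 10 fibroblast markers had a higher Tg-Sirt1 mean (median 0.26, camera adjusted p = 0.0664, and 0.991 with an estimated correlation of 0.895), including Pdgfra (0.33), Lum (0.42) and Tcf21 (0.44). Without NTg 2 these 3 were 0.07, -0.07 and -0.10. The medians were -0.04 for cardiomyocyte markers, 0.03 for atrial and conduction myocardium, -0.05 for endothelial, 0.01 for smooth muscle and pericyte, 0.12 for macrophage and monocyte, -0.05 for T cell, -0.04 for B cell and plasma cell, and 0.16 for erythroid markers. They were 0.04 for mesothelium and epicardium, -0.06 for white and brown adipocyte, -0.10 for skeletal muscle, -0.04 for lung, thymus and liver carry-over and -0.005 for sex-specific transcripts. Median and mean differed in sign for the lists of fetal and hypertrophy genes, cardiac ion channels, FoxO-regulated genes, atrial markers, smooth muscle markers, B cell markers and sex-specific transcripts, and median and camera direction did for FoxO-regulated genes, immediate early genes, atrial markers, smooth muscle markers and sex-specific transcripts. The median changed sign under a second quantile normalization or after centring in 15 of the 44 lists, each with a median of at most 0.055 in size and 0 of them past the threshold.

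Tg-Sirt1 2 and NTg 2, the arrays outside the near-identical pair, were far apart, and genes such as Clca4a and Acta1 stood apart on NTg 2 while Nipbl and Srrm2 stood apart on Tg-Sirt1 2. NTg 1 lay nearer to Tg-Sirt1 2 than to NTg 2 at 73.6% of the probe sets higher on Tg-Sirt1 2, and at 12.9% of those lower there. This comparison has 1 array on each side, no replicate check and no test, and it was added after seeing the data. Of 1101 probe sets over 2-fold apart, 588 were higher and 513 lower on Tg-Sirt1 2. With each array centred on its median the numbers were 780 and 433, and after a second quantile normalization 559 and 585, so the balance depended on the scaling. Of the 588, 187 were also over 2-fold higher on NTg 1 than on NTg 2, and 41 were over 2-fold above the array labelled Tg-Sirt1 1. Of the 513, 373 were over 2-fold below the array labelled Tg-Sirt1 1, and 51 were also over 2-fold lower on NTg 1 than on NTg 2.

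The largest difference on the higher side was in Clca4a, which read 5.72 on NTg 2 and 10.06, 10.04 and 10.58 on NTg 1, Tg-Sirt1 1 and Tg-Sirt1 2. Bex1 read 7.42 on NTg 2 and 10.86 to 11.28 on the other 3 arrays, and the slow skeletal troponin gene Tnnt1 read 7.43 and 10.92 to 11.16. The tubulin gene Tubb2b, the monocarboxylate transporter gene Slc16a7, Ndnf, the amino acid transporter gene Slc38a1, Slc24a2, Septin6, Snap91, Tchhl1 and Rps4l likewise read lowest on NTg 2, with differences of 2.87 to 3.52 between Tg-Sirt1 2 and NTg 2. On the lower side, Acta1 differed by -5.71. Pdk4, the kinase gene that restrains pyruvate dehydrogenase, read 13.01 on NTg 2 and 10.26 to 10.55 on the others, and Cyp2b10 read 8.40 and 5.81 to 5.96. Myh7 (-2.38) and Gdap10 (-2.63) were among the largest differences too. The cohesin loader gene Nipbl (5.88, against 9.26 on NTg 1), Srrm2 (6.47, against 9.55 to 9.96), Actb (9.47, against 12.01 to 12.88), Phf20l1, Dhx36 and Ubn1 were low on Tg-Sirt1 2 alone, and Map3k12 was lowest there (6.56) and highest on NTg 2 (8.78).

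The lists also differed between arrays of one label. The fatty acid oxidation and PPAR list had a median of -0.25 for Tg-Sirt1 2 minus NTg 2, below all of 10000 matched random lists, and of -0.17 for NTg 1 minus NTg 2, also below all of them, but of -0.02 for Tg-Sirt1 2 minus the array labelled Tg-Sirt1 1. The fibroblast list had a median of 0.52 for Tg-Sirt1 2 minus NTg 2 and of 0.85 for NTg 1 minus NTg 2. Extreme ranks were common. For NTg 1 minus NTg 2 the FoxO list stood at percentile 0 and the fibroblast and extracellular matrix lists at 100. For Tg-Sirt1 2 minus NTg 2 the oxidative phosphorylation list stood at 0.37 with a positive median of 0.07. Between the 2 Tg-Sirt1 arrays, Tg-Sirt1 2 minus Tg-Sirt1 1, the atrial and conduction list stood at 100 (median 0.51). In the same difference the extracellular matrix list stood at 0 (-0.32), the endothelial list at 0.06 (-0.36) and the smooth muscle and pericyte list at 0.09 (-0.33). Genes drawn at random lack the shared variation of a list's members, so these ranks are not a test. For Tg-Sirt1 1 minus NTg 1 the median of each of the 44 lists was at most 0.05 in size.

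**Figure D4:**
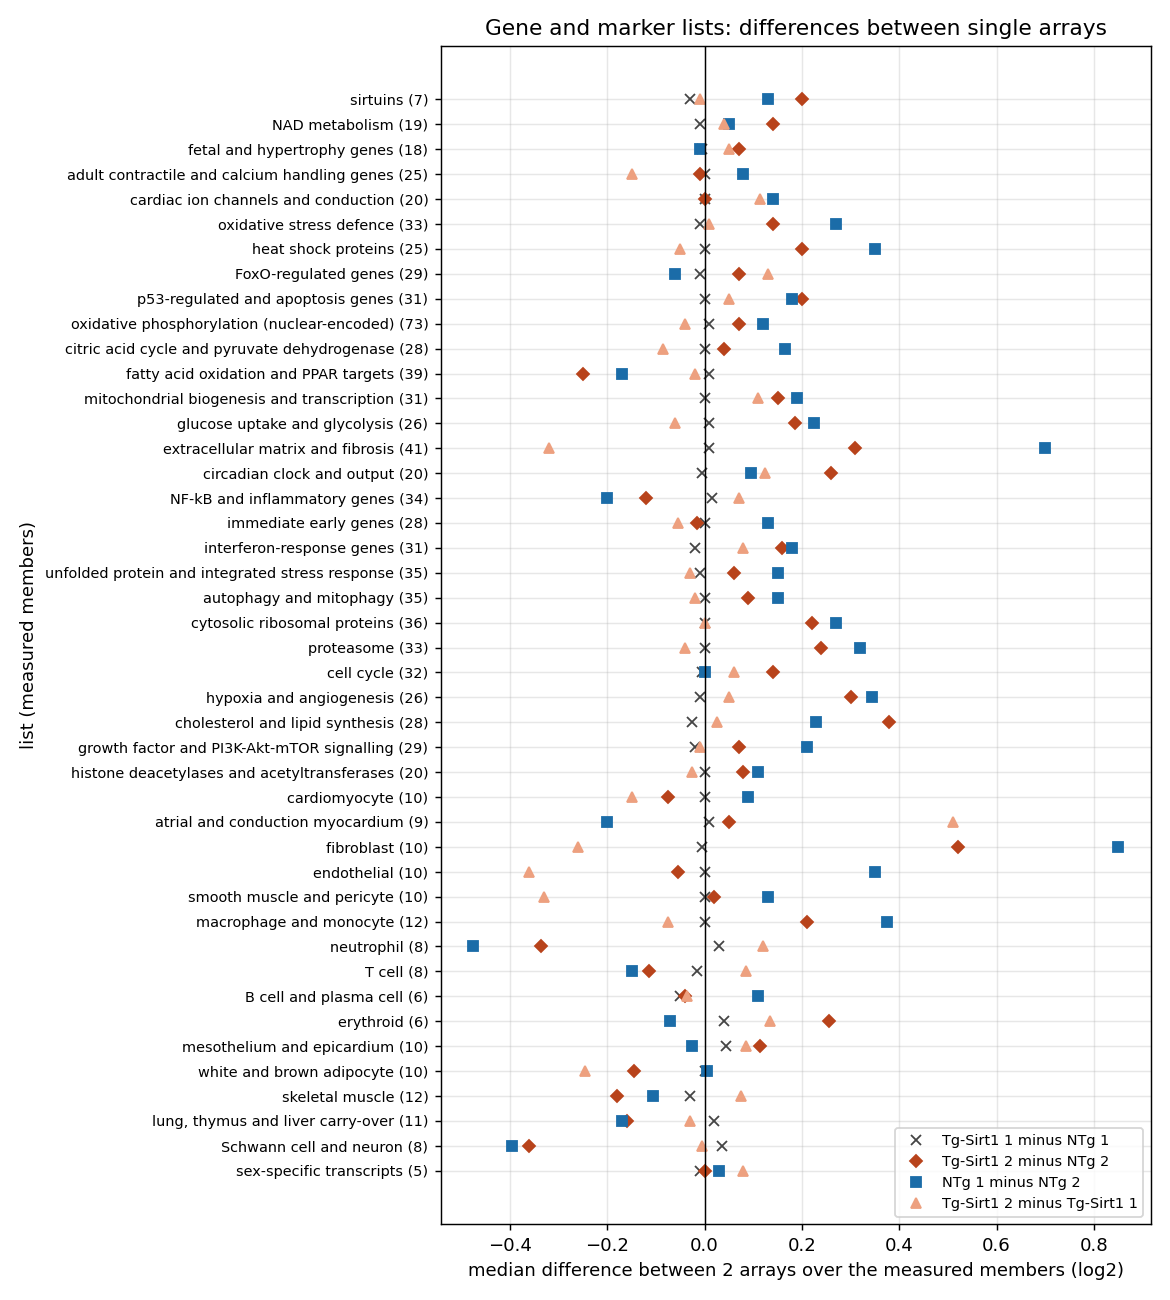
Median log2 difference between 2 single arrays over the measured members of each of the 44 lists, for Tg-Sirt1 1 minus NTg 1 (crosses), Tg-Sirt1 2 minus NTg 2 (diamonds), NTg 1 minus NTg 2 (squares) and Tg-Sirt1 2 minus Tg-Sirt1 1 (triangles). The crosses lie within 0.05 of 0, and the squares and diamonds reach 0.85 and 0.52 for fibroblast markers.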

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

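The tests of the near-identical pair and of the transgene on Tg-Sirt1 2 were chosen after the results were seen. The tests of paired probe sets and of array scaling were written down before they were run.

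The 3' minus 5' control signals, which no comparison used, were higher on Tg-Sirt1 2 than on both NTg arrays for 2 of 4 control genes. Actb gave 1.92 log2 units, against 1.22 on NTg 1, 1.44 on NTg 2 and 1.25 on the array labelled Tg-Sirt1 1. Gapdh gave 1.34, against 0.18, 0.69 and 0.19. For Tg-Sirt1 2 minus the array labelled Tg-Sirt1 1, the Actb 3' control itself gave -1.64 and the 5' control -2.31, so most of the Actb difference was not specific to the 5' end, while Gapdh gave -0.20 and -1.35. Pcx gave 1.19, against 1.47, 0.87 and 1.41, and Tfrc gave 2.64, against 2.64, 2.04 and 2.61, so these 2 genes did not stand apart on Tg-Sirt1 2.

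On Tg-Sirt1 2, 833 probe sets were over 2-fold lower than on the array labelled Tg-Sirt1 1, against 78 that were over 2-fold higher. The medians of 6.22 on Tg-Sirt1 2 and 6.24 on the array labelled Tg-Sirt1 1 cannot decide on a shift of the whole array, because RMA quantile normalizes the arrays. The spike-in control probe sets had a mean of 8.77 on Tg-Sirt1 2 and 10.11 on the array labelled Tg-Sirt1 1. On NTg 1 and NTg 2 their mean was 10.12 and 10.88. After another quantile normalization the median change of the 833 was -1.33, against -1.41 before. This could hardly decide on array scaling, as the deposited values were already quantile normalized and the 833 were picked for a low value. For 614 of them another, brighter probe set of the same gene was on the array, with a median change of 0.02, and the median share of the change that it showed was -0.0161 (95% bootstrap interval -0.0335 to -0.0038), which is consistent with less signal from one part of many transcripts, as a loss of 5' signal would give. The positions of probe sets were not used here, so another loss that hits one probe set of a gene stays open. The transgene cannot be told apart from the state of this RNA, because the same probe sets differed by a median of -0.01 between the array labelled Tg-Sirt1 1 and NTg 1, and the label of that pair is in doubt.

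The arrays labelled NTg 1 and Tg-Sirt1 1 had a rank correlation of 0.9989 across probe sets, against 0.9773 to 0.9849 in the other 5 pairs. Quantile normalization of the probe set values would not alter their ranks, so this argues against such a rescaling as the cause. RMA normalizes single probes before it summarises them, so the ranks cannot decide on the authors' processing as a whole. The 18 spike-in control probe sets differed by a median of 0.02 log2 units, against 0.86 to 2.25 in the other pairs. A single RNA preparation or hybridisation mixture measured under both labels would give such values. A copy of 1 array's values under both labels is argued against: copies would be equal, while the pair differed by up to 0.48 log2 units. Separate hearts of one kind stay open, since no pair is known to be such hearts prepared together to set the SD of 0.0759 against. Whether the array labelled Tg-Sirt1 1 is the mislabelled one cannot be told: Sirt1 on the pair lay 0.06 above NTg 2, where Tg-Sirt1 2 lay 0.76 above it, but NTg 1 was nearer to Tg-Sirt1 2 than to NTg 2 at 73.6% of the 588 probe sets higher on Tg-Sirt1 2. Those 588 were taken because many probe sets were lower on Tg-Sirt1 2 for a reason that is not settled. This was only after NTg 1 proved nearer at 45.3% of all 1101 probe sets and at 12.9% of the lower ones. Over all 1101 the criterion for a mislabelled Tg-Sirt1 1 would have been met.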

How the results depend on the processing

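The fits that counted the near-identical arrays once and all values for Tg-Sirt1 2 against NTg 2 alone were chosen after seeing the data, and the other settings before. In limma, 0 probe sets and 0 genes passed in every setting run, including an adjusted p of 0.1. The probe sets at an unadjusted p under 0.05 went from 28 to 4 without dim probe sets, 122 with a trend and robust prior and 472 in the unmoderated test. Their number varied far more widely over the fits that left 1 array in a label. A fit without 1 array, or with the pair counted once, takes the lone array to vary like the other label. Without Tg-Sirt1 2, the Tg-Sirt1 label keeps only the near-identical partner of NTg 1, so that fit nearly compares the 2 NTg arrays. The Sirt1 fold change ran from -0.075 to 0.695 over the fits without 1 array and was 0.76 between Tg-Sirt1 2 and NTg 2. The number of lists past the threshold, 4, ran from 1 (without the array labelled Tg-Sirt1 1) to 15 (without Tg-Sirt1 2), with 12 without NTg 1. It was 2 after quantile normalization, 2 without _x_at and _s_at probe sets, 0 in camera with an estimated correlation, 1 with a correlation of 0.05, 0 in fry, and 1 or 12 with the pair counted once as NTg or as Tg-Sirt1. Over the fits without 1 array, the median ran from -0.005 to 0.2575 for ribosomal proteins, -0.3875 to 0.065 for neutrophil markers and -0.3575 to 0.035 for Schwann cell and neuron markers, and the fold change from -0.235 to 0.305 for Nppa, -0.065 to 0.005 for Myh6, -0.275 to 0.165 for Ppargc1a, -0.695 to 0.065 for Cat and -0.04 to 0.05 for Sod2. Nppa was -0.0337 after quantile normalization and -0.213 with the pair as Tg-Sirt1, Sod2 -0.0519 after quantile normalization and -0.0525 as a mean of probe sets, Myh6 0.005 after centring, and Ppargc1a 0.117 as a mean of probe sets and 0.0975 with the pair as Tg-Sirt1. For these changes of sign and number the cause was not tested. Of 446 alternative values of the 30 other named genes, 418 kept their sign and stayed above an adjusted p of 0.05, 0 passed, 15 changed sign, and 13, of the single-array difference, moved by over 1 SD. Sizes were less stable than signs: for 29 of the 30 genes at least 1 of the 4 fits without 1 array moved the fold change by over 1.5 times (14 without NTg 1, 19 without NTg 2, 12 without the array labelled Tg-Sirt1 1, 18 without Tg-Sirt1 2), with Acta1 from -5.325 to -0.525, Myh7 from -2.005 to -0.385, Cdkn1a from -1.505 to -0.175 and Nppb from -0.805 to -0.105. A fold change nearly equals the sum of its values without NTg 2 and without Tg-Sirt1 2, because of the near-identical pair. At least 1 move of this size was thus nearly fixed in advance. As a mean of probe sets Myh6 was -0.5325. The count of 1101 probe sets over 2-fold apart between Tg-Sirt1 2 and NTg 2 ran from 800 to 1213. The labels do not say whether the replicate numbers pair the mice, and 2 pairs are too few to settle it from the values, so they were treated as sharing only a number. Deviations of same-numbered arrays correlated at 0.293 across probe sets. Because NTg 1 and Tg-Sirt1 1 were near-identical, the 2 sets of deviations share nearly the same values. A positive correlation was thus nearly fixed in advance and does not bear on pairing. With the replicate block, which rests on the same pair, 0 probe sets and 0 genes passed. The Sirt1 fold change was then 0.31 (limma adjusted p = 0.931) and 6 lists passed. Signal over background is not given, so that the limit for dim probe sets is unknown.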

Other observations

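The single-array values here and the tests of NTg 2 for skeletal muscle, for the transgene and for its lower probe sets apart were chosen after the results were seen, as were the splits. The test of paired probe sets over all those of NTg 2 was written down before it was run.

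Beyond the genes described above, some members of the lipid, matrix and heat shock lists stood apart on NTg 2. These genes were chosen after their values were seen, and the values are of single arrays and were not tested. The PPAR targets Acot1 and Angptl4 read 8.48 and 9.22 on NTg 2, against 6.38 to 6.57 and 6.97 to 7.36 on the other 3 arrays, and the mitochondrial carrier gene Ucp3 read 9.40 against 8.13 to 8.35. The fatty acid synthase gene Fasn read 7.12 on NTg 2 against 8.36 to 9.01 and Scd2 read 7.67 against 8.80 to 8.83, while the whole cholesterol and lipid synthesis list had a median of 0.23 for NTg 1 minus NTg 2, at percentile 92.9 of matched random lists. The collagen genes Col3a1 and Col1a1 read 10.61 and 9.18 on NTg 2, against 11.32 to 11.88 and 9.58 to 10.51. The chaperone genes Hsph1 and Dnaja1 read 8.81 and 9.11 on NTg 2, against 10.23 to 10.37 and 10.01 to 10.16, while the chaperone gene Hspb7 was highest on NTg 2 (12.88, against 11.55 to 12.29). The clock output gene Dbp read 9.79 on NTg 2 against 11.18 on Tg-Sirt1 2. Among atrial and conduction genes, Myl7 read 11.78 and the sarcolipin gene Sln 11.36 on Tg-Sirt1 2, against 10.89 to 11.09 and 10.60 to 10.95 on the other 3 arrays. Shox2 was highest there too (6.78, against 5.65 to 5.78). Nr2f2 (5.91, against 7.34 to 7.37), Tbx5 (7.19, against 7.97 to 8.03) and Stard10 (8.61, against 8.94 to 9.18) were lowest there. The median of this list was 0.51 for Tg-Sirt1 2 minus the array labelled Tg-Sirt1 1, but 0.05 for Tg-Sirt1 2 minus NTg 2.

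At 238 probe sets NTg 2 lay over 2-fold apart from NTg 1 and from Tg-Sirt1 2 in the same direction, 51 higher and 187 lower. Skeletal muscle in the sample is argued against, because the 10 skeletal muscle markers other than Acta1 and Ckm differed by a median of 0.105 between NTg 2 and NTg 1 while Acta1 differed by 4.80, although Casq1 was 2.09 higher and Myl1 went the other way (-1.20). A loss of 5' signal stays open for the 187 lower probe sets, where the brighter partners of 44 showed a median share of 0.631 of the change (95% bootstrap interval 0.412 to 0.762). A share of 0.593 (0.352 to 0.723) over 59 partners also counted those of the 51 higher probe sets, to which the test does not apply, because a loss of signal on NTg 2 lowers values. The transgene stays open as well: NTg 1 was nearer to Tg-Sirt1 2 than to NTg 2 at 45.3% of the probe sets over 2-fold apart between those 2 arrays, and no bound can be set while the label of NTg 1 is in doubt. The age, feeding and time of day of the mice may differ between hearts and were not tested, and the Y-linked Eif2s3y (7.08 to 8.05) and Kdm5d (7.21 to 7.91) and Xist (6.94 to 7.32) each stayed within 1 log2 unit over the 4 arrays.

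The 4 arrays make 3 splits into 2 and 2, too few for a share under 0.05. All 3 splits gave at least the 28 probe sets at an unadjusted limma p under 0.05 that the labels gave. The highest other count, 6264, came from NTg 1 and Tg-Sirt1 1 against NTg 2 and Tg-Sirt1 2. This points to a structure of the samples, the near-identical pair. In camera 19 lists passed under that split and 5 under the remaining one, against 4 under the labels. The number of lists past the threshold thus does not set the labels apart from other groupings.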
